A study of Mus musculus with 18 samples.

How the data were processed

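RNA from mouse embryonic fibroblasts (MEFs, connective tissue cells grown from embryos) of 3 genotypes was hybridised to Affymetrix GeneChip Mouse Exon arrays, which carry probe sets for single exons across the genome. The genotypes were AGO2 null, Dicer null and wild type, with 3 arrays each. Ago2 encodes the Argonaute protein that binds and cuts targets of small RNAs, and Dicer1 encodes the enzyme that makes mature microRNAs from their precursors. Per the labels, cells were grown for 3 days in medium with 7% fetal calf serum and RNA was labelled with a NuGEN Applause kit. Each of the 9 arrays entered as 2 samples, a gene-level and an exon-level table, giving 18 samples in all. The Dicer null and wild-type lines came from one source and the AGO2 null line from another, per the labels. Each genotype was 1 line as far as the labels say, and the labels call the arrays biological replicates or triplicates without naming separate lines or animals. The p-values therefore measure the spread between these samples, which may be technical.

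The authors deposited log2 values, 1 column per sample, in a gene-level table of 23332 rows and an exon-level table of 229581 probe sets. Background correction, summarisation, normalization and filters used to make these values are not given in the sources used here, and mm8 is the only genome build named in the submitters' processing notes. The values were used as deposited, and no probe coordinates are given. A total of 6577 rows occurred in both tables, and all were equal, within a tolerance of 1e-04, in the columns of the same array. Gene symbols came from the annotation of the array platform, updated through gene identifiers and synonyms of the RefSeq table of mouse assembly GRCm38.p6, which was used for names only. At the gene level 14996 rows had 1 symbol, 1019 had several and 7317 had none; 14941 rows matched the RefSeq table by gene identifier. At the exon level 209279 probe sets had 1 symbol, 4446 several and 15856 none; 208810 matched. No gene was named from a row with several symbols.

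Gene-level differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) on the log2 values of all 9 samples with group means as the only terms. A row was called at a Benjamini-Hochberg adjusted p under 0.05 over the 23332 rows, and counts with an absolute log2 difference of at least 1 (2-fold) are given beside it. Exon usage was measured with the splicing index, the log2 value of a probe set minus the median of all probe sets of its gene in the same sample. It was tested with the same limma model over 114158 probe sets of 7832 genes. These were the genes with at least 4 probe sets and a level at or above the median, and among their probe sets those at or above the 25th percentile. Because the index subtracts the gene's level, a probe set that does not respond to its gene receives an index difference of the opposite sign when the gene changes.

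Gene lists were tested with limma's camera, which compares a list with the other genes, out of 14847 named by rows with 1 symbol. Each gene entered with 1 row, that of the highest mean over the 9 samples. Camera was run at the preset correlation of 0.01 and again with an estimated correlation. The lists were also tested with fry, which makes no comparison with other genes. Its directional p asks whether the genes of a list move, on balance, one way. The 23 lists were RNA silencing machinery, splicing factors, chromatin silencing factors, let-7 targets, miR-17 and miR-21 family targets, interferon-stimulated genes, p53 targets, cell cycle genes, extracellular matrix, contractile and smooth muscle genes, Hox genes, imprinted genes, sex-linked genes, cholesterol biosynthesis, fibroblast identity genes, genes with known alternative exons, and markers of epithelial cells, macrophages and leukocytes, endothelium, neural and glial cells, skeletal muscle, adipocytes with cartilage or bone, and pluripotent and germline cells. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the targeted genes Ago2 and Dicer1, and per comparison the 10 largest rises and 10 largest falls among called rows with 1 symbol whose samples did not overlap between groups. It also took up to 2 members of each list with the largest rise and 2 with the largest fall among those called, the 10 probe sets with the largest index differences, and probe sets of Cd44 and of up to 5 genes with known alternative exons. A further 6 lists were written after the gene-level values had been seen, and were tested without the genes that this rule had named. No detection measure was used here, so a difference against a dim value depends on the floor of its probe set, and the order of large differences can depend on it too.

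Both null lines were compared with the same 3 wild-type samples, so the overlap of the comparisons was set beside simulations of unchanged groups (20 for the gene level, 10 for exon usage) and beside the overlap of independent lists. Alternatives covered quantile normalization, median centring, an offset of 50 added on the linear scale, filters on dim rows, the variance model, fits of the 6 samples compared, the replicate number as a block, gene levels taken from the exon-level table, limma's diffSplice test and leaving out each replicate. On simulated data for AGO2 null against wild type, the gene-level test over 23332 rows recovered 46.3%, 74.6% and 90.3% of log2 changes of 0.5, 1 and 2, and the exon usage test over 113848 probe sets recovered 1.6%, 23.5% and 89.7%. For Dicer null against wild type the shares were 47.8%, 80.3% and 93.5% at the gene level and 3.1%, 34.3% and 89.8% over 113744 probe sets. The simulated data held few changed features, with 148 gene-level and 72 exon usage calls for AGO2 null against wild type, far fewer than the real data. An adjusted threshold is stricter with few calls, so these shares are not the recovery in the real data. The number of arrays limits the precision. Data were handled with the R package data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9. No other columns of values were left out, and the sequence of the deleted parts of Ago2 and Dicer1 was not used here.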

Results

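The series measured steady-state RNA of mouse embryonic fibroblasts that lacked AGO2 or Dicer and of wild-type cells, at the level of genes and of single exons. Its title concerns Argonaute proteins, chromatin silencing and alternative splicing, so both gene level and exon usage were compared between genotypes. Each genotype had 3 arrays. Median log2 values were close across samples, from 6.28 to 6.37 in the gene-level table and from 6.93 to 7.10 in the exon-level table. Correlations across rows of the gene-level table were 0.985 to 0.993 within genotypes and 0.957 to 0.972 between them, where rows are not independent replicates. The first principal component held 46.9% of the variance and the second 27.7%. The median replicate SD of a gene-level row was 0.126 in AGO2 null, 0.075 in Dicer null and 0.106 in wild-type cells.

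The targeted genes followed the labels in every sample. Ago2 was 6.77 ± 0.14 (log2, SD, n = 3) in AGO2 null cells against 8.23 ± 0.02 in the wild type, and single samples stood at 6.74, 6.92 and 6.65 against 8.24, 8.20 and 8.24. The difference was -1.46 (SE 0.08, limma adjusted p = 1.27e-05). Of the 21 Ago2 probe sets in the exon-level table, 19 were called lower in AGO2 null cells, with a median difference of -1.46 and a range from -2.84 to -0.22. Dicer1 was 8.37 ± 0.04 in Dicer null cells (8.42, 8.35 and 8.35) against 9.18 ± 0.02 in the wild type (9.17, 9.17 and 9.20), a difference of -0.80 (SE 0.04, adjusted p = 4.42e-06). Of its 40 probe sets, 33 were called lower, with a median difference of -0.82. Dicer1 probe set 4609131 fell from 8.82 ± 0.08 to 6.05 ± 0.15, further than its gene (splicing index difference -2.08, adjusted p = 5.95e-05). The deleted exons were not matched to probe sets, so remaining signal at both genes could not be assigned to parts inside or outside the deletions.

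Each null line also differed at the other gene. Ago2 stood at 9.14 ± 0.10 in Dicer null cells (9.23, 9.15 and 9.04), 0.91 above the wild type (adjusted p = 8.51e-05), and 18 of its 21 probe sets were called higher there. Dicer1 stood at 9.40 ± 0.01 in AGO2 null cells (9.40, 9.42 and 9.39), 0.23 above the wild type (adjusted p = 0.00628). That small rise was not past the threshold after quantile normalization (0.13). As the median of the gene's exon probe sets the rise was 0.30. The median itself was not tested, and 6 of the 40 probe sets were called higher.

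**Figure D1:**
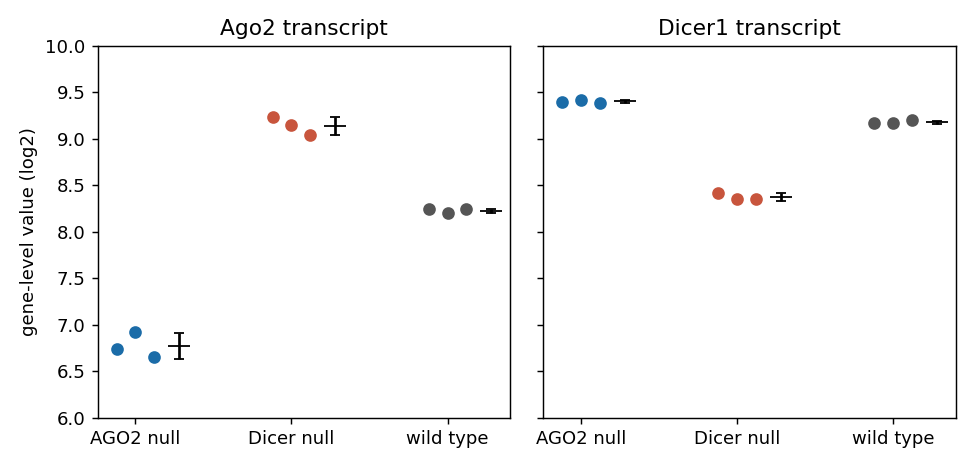
Gene-level log2 values of Ago2 and Dicer1, with a point per sample for the 3 genotypes and the mean with its SD (n = 3). Ago2 is lowest in AGO2 null cells at 6.77 and highest in Dicer null cells at 9.14, and Dicer1 is lowest in Dicer null cells at 8.37.

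In AGO2 null against wild-type cells Saa3, an acute-phase apolipoprotein, rose by 6.02 on the log2 scale (SE 0.10, adjusted p = 9.41e-08), from 5.50 ± 0.16 to 11.52 ± 0.13 (n = 3 each). Lpl, the lipase that hydrolyses lipoprotein triglycerides, rose by 4.27, and Aldh1a2, which makes retinoic acid, by 4.09. The retinoic acid binding proteins Crabp1 and Crabp2 were lower, at -4.37 and -3.78, as was the imprinted non-coding RNA H19 at -4.39 (adjusted p = 2.05e-07). The urea transporter Slc14a1 differed by -4.83 (SE 0.19, adjusted p = 2.42e-06).

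Other large rises were those of the TNF family ligand Tnfsf18 (4.91), the scavenger receptor Olr1 (4.28), the cholinesterase Bche (4.19), the adhesion molecule Cadm1 (4.13), Rtn1 (4.03), the monooxygenase Fmo2 (4.02) and the peptidase Dpp4 (4.0). Olr1 varied between AGO2 null samples, at 9.81 ± 1.30. Large falls included the opioid precursor Penk (-4.80), the TIE2 ligand Angpt1 (-4.32), the transcription factor Mecom (-4.28, in the more strongly changed of its rows), the peptidase Mme (-3.79), Itm2a (-3.78) and the G protein regulator Rgs2 (-3.77).

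Interferon-stimulated genes were mostly lower in AGO2 null cells. Of 36 measured, 19 fell, 2 rose and 15 did not pass the test (22 and 2 adjusted over the list alone), with Ifit1 at -1.47 and the GTPase Mx1 at -1.43, while Trim30a (1.94) and Ifi27l2a (1.30) rose. The list median was -0.34 (camera adjusted p = 7.02e-07, adjusted p = 0.878 with an estimated correlation). Extracellular matrix genes had more members higher than lower, with 29 of 58 higher, 12 lower and 17 not called (32 and 13 adjusted over the list alone). The collagenase Mmp13 (2.54) and the hyaluronan synthase Has2 (2.16) rose, and Fbn2 (-1.90) and Col6a3 (-1.51) fell. The matrix list passed with a median of 0.25 (camera adjusted p = 0.00976), but had adjusted p = 0.878 with an estimated correlation and camera adjusted p = 0.158 with rows below the median level left out.

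Targets of microRNAs had more members higher than lower in AGO2 null cells, without passing camera. Among 33 let-7 targets 14 rose, 5 fell and 14 did not pass (16 and 7 adjusted over the list alone), including the death receptor Fas (1.58), the kinase Cdk6 (1.47), Ccnd1 (-1.03) and Prtg (-0.97), with a median of 0.22 and camera adjusted p = 0.197. Among 21 targets of the miR-17 and miR-21 families 9 rose and 2 fell, also when adjusted over the list alone, with Timp3 at 1.83, Zfpm2 at 1.32 and Cdkn1a at -0.98 (camera adjusted p = 0.197). In the RNA silencing machinery, which holds Ago2 and Dicer1 themselves, 7 of 38 genes rose and 5 fell (8 and 7 adjusted over the list alone; 6 and 4 without the targeted genes). These included Ago3 (0.48), which lost its call in the fit of the 6 samples compared, and the RNA editing enzyme Adar (-0.67). Splicing factors numbered 12 higher and 10 lower of 55 (20 and 11 adjusted over the list alone), led by Mbnl3 (1.57) and Celf2 (1.05), and chromatin silencing factors 4 higher and 5 lower of 34, the same adjusted over the list alone, with the DNA methyltransferase Dnmt3a at 0.46 and the deacetylase Sirt1 at -0.35. A second row of Celf2 was not called (0.58, limma adjusted p = 0.142). After quantile normalization the splits turned to 2 higher and 8 lower for RNA silencing and 6 higher and 13 lower for splicing factors.

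Genes of position and identity changed in both directions. Of 32 Hox genes 8 rose and 7 fell (11 and 8 adjusted over the list alone), with Hoxc8 (1.79) and Hoxc6 (1.64) higher and the distal Hoxd13 (-3.27) and Hoxd10 (-2.96) lower. Fibroblast identity genes split 8 to 7 of 29 (9 to 9 adjusted over the list alone), with the transcription factor Tcf21 (2.79) and the growth factor Igf1 (2.10) higher and the limb factor Tbx5 (-2.47) lower. Among 23 imprinted genes 4 rose, including the proteoglycan Dcn (1.5), and 7 fell, including Igf2 (-2.07), also when adjusted over the list alone. Contractile genes rose in 7 and fell in 4 of 20 (7 and 5 adjusted over the list alone), led by the myosin kinase Mylk (2.47). Cell cycle genes numbered 6 higher and 10 lower of 44 (6 and 13 adjusted over the list alone), with Mki67 at -0.55, and p53 targets 4 and 7 of 26 (4 and 10). Cholesterol biosynthesis had 4 of 18 genes higher and none lower, also over the list alone. Among 81 genes with known alternative exons 21 rose and 18 fell (29 and 23 adjusted over the list alone), turning to 18 and 25 after quantile normalization. The sex-linked genes Eif2s3y (0.48) and Kdm5d (0.45) were higher among 3 measured, Kdm5d not after quantile normalization.

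Markers of other cell types moved in few genes of AGO2 null cells. Epithelial markers included higher Krt19 (3.90) and Krt14 (1.65) and lower Perp (-0.66), with 3 of 19 higher and 1 lower (4 and 1 adjusted over the list alone). Macrophage and leukocyte markers had 1 higher and 1 lower of 18 (0 and 1), with Cd68 at -0.77, and endothelial markers 1 and 1 of 16 (1 and 1), with Kdr at 1.25 and Erg at -1.78. Neural and glial markers had 3 higher and 4 lower of 19 (4 and 5), with Stmn2 at -2.80. Skeletal muscle markers had 2 higher and 1 lower of 18 (2 and 1), with Tnnt2 at 1.91. Adipocyte, cartilage and bone markers had 3 higher of 20 (3 and 0), Lpl among them, and pluripotency and germline genes 3 higher and 1 lower of 26 (3 and 1), with Sox2 at -1.01. None of the lists in this and the preceding paragraph passed camera, where the lowest adjusted p was 0.197, that of p53 targets. After quantile normalization cell cycle genes passed (0.00153), with 4 higher and 18 lower, and p53 targets had 4 higher and 11 lower. Cholesterol biosynthesis passed without AGO2 null replicate 2 (1.65e-05).

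In all, 4903 of 23332 rows (21%) were called between AGO2 null and wild-type cells, 2764 higher and 2139 lower, and 974 of them differed at least 2-fold. The higher share of calls was 56.4%, and 45.6% after quantile normalization. The groups did not overlap in 33.2% of rows, where chance gives 10%. The median, the mean and the camera direction differed in sign for chromatin silencing factors, Hox genes, fibroblast identity genes and the leukocyte, neural and skeletal muscle markers. With an offset of 50, 520 rows differed at least 2-fold. Camera called 2 of the 23 lists and fry 13, and 0 passed camera with an estimated correlation (0 at an unadjusted p under 0.05), where the lowest adjusted p was 0.878. Where limma called 0 list members in a direction, 0 passed at an unadjusted p under 0.05 as well, except 1 lower adipocyte, cartilage or bone marker.

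In Dicer null against wild-type cells Postn, a matrix protein of connective tissue, fell by 6.34 on the log2 scale (SE 0.05, adjusted p = 1.13e-09), from 10.26 ± 0.03 to 3.92 ± 0.04 (n = 3 each), and the growth factor Fgf7 also fell by 6.34 (SE 0.20, adjusted p = 4e-07). The limb mesenchyme factor Prrx1 fell by 5.43 and the interferon-induced Ifit1 by 5.86. The keratin Krt18 rose by 4.30, from 7.31 ± 0.16 to 11.61 ± 0.06, and the cardiac troponin gene Tnnt2 by 5.01. The leukotriene receptor Cysltr1 rose by 5.13 (SE 0.20, adjusted p = 9.67e-07), from a dim wild-type value of 4.61.

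Further large rises were Tmem255a (4.92), the lipopolysaccharide binding protein Lbp (4.66), the ganglioside synthase St8sia1 (4.60), Cadm1 (4.39), Tcf21 (4.19), the convertase Pcsk5 (4.16) and Rtn1 (4.13). In its other row St8sia1 rose by 2.18. Further large falls were Itm2a (-5.97), Mecom (-5.71), the matrix protein Aspn (-5.68), Angpt1 (-5.47), Crabp1 (-5.42) and Gas2 (-5.35).

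Of 36 interferon-stimulated genes 34 fell, 0 rose and 2 did not pass limma's test (34 and 1 adjusted over the list alone), with Ccl5 at -4.17. The list median was -1.58 (camera adjusted p = 4.18e-17, adjusted p = 0.184 with an estimated correlation). Macrophage and leukocyte markers numbered 1 higher (Csf1r, 1.11) and 2 lower of 18, also over the list alone, with Cd68 at -0.75. Extracellular matrix genes fell in 35 and rose in 13 of 58 (36 and 14 adjusted over the list alone), with the laminin Lama4 at -4.37 and Timp3 at 1.36, a median of -0.65, camera adjusted p = 6.46e-06 and adjusted p = 0.194 with an estimated correlation. Fibroblast identity genes fell in 16 and rose in 5 of 29, also over the list alone, with Wt1 (2.55), a factor of mesothelium and kidney, among those higher. Their median was -1.06 (camera adjusted p = 0.00072, adjusted p = 0.0731 with an estimated correlation), and camera adjusted p was 0.0788 with rows below the median level left out. Contractile genes fell in 13 of 20 and rose in 3 (13 and 4 adjusted over the list alone), with Actg2 at -3.18, Csrp2 at -3.04 and Mylk at 2.16 (camera adjusted p = 0.0149, adjusted p = 0.494 with an estimated correlation).

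Hox genes fell in 20 of 32, with 1 higher and 11 not called (21 and 1 adjusted over the list alone), with Hoxd13 (-3.65) and Hoxd10 (-2.81) among those lower. The Hox median was -0.35 (camera adjusted p = 0.00026, adjusted p = 0.0731 with an estimated correlation). Let-7 targets rose in 19 and fell in 7 of 33 (21 and 8 adjusted over the list alone), with a median of 0.47. The nuclear receptor Nr6a1 (2.28) and the RNA binding protein Lin28a (2.10), which blocks let-7 maturation, rose, and Col1a2 (-3.68) and Thbs1 (-1.32) fell. The let-7 list had camera adjusted p = 9.26e-05 and adjusted p = 0.194 with an estimated correlation. Targets of the miR-17 and miR-21 families were divided, with 7 higher and 8 lower of 21 (8 and 8 adjusted over the list alone; 9 higher and 7 lower after either scaling), Zfpm2 at 1.10 and Tgfbr2 at -1.60 (camera adjusted p = 0.562). Cholesterol biosynthesis genes rose in 9 of 18 and fell in none (12 and 0 adjusted over the list alone), with the cyclase Lss at 1.00, a median of 0.54, camera adjusted p = 9.26e-05 and adjusted p = 0.613 with an estimated correlation.

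Splicing factors rose in 12 and fell in 6 of 55, also over the list alone, with Mbnl3 at 0.95, Celf2 at 0.89 and Khdrbs3 at -1.60, a median of 0.11, camera adjusted p = 0.00159 and adjusted p = 0.494 with an estimated correlation. A second row of Celf2 was not called (0.72, limma adjusted p = 0.0633). After median centring 25 splicing factors rose and 4 fell. In the RNA silencing machinery 11 of 38 rose and 8 fell (11 and 9 adjusted over the list alone, 10 and 7 without Ago2 and Dicer1), with Tnrc6b, a partner of Argonaute proteins, at 1.05 in the more strongly changed of its rows and Adar at -1.24 (camera adjusted p = 0.065, or 0.0338 without wild type replicate 3). Chromatin silencing factors had 6 higher, such as Jarid2 (0.75), and 7 lower, such as Uhrf1 (-0.70), of 34 (7 and 7 adjusted over the list alone). That split became 9 and 6 after quantile normalization and 10 and 3 after median centring. Imprinted genes included higher Peg3 (2.77) and lower H19 (-4.61) and Ndn (-3.47), with 5 higher and 8 lower of 23 (5 and 9). Cell cycle genes had 8 higher and 7 lower of 44 (12 and 10; 13 and 7 after median centring), p53 targets 6 higher and 9 lower of 26 (7 and 10), with Perp at 2.27, and the sex-linked genes Kdm5d (-0.93) and Eif2s3y (-0.72) fell among 3. Genes with known alternative exons rose in 12 and fell in 29 of 81 (20 and 29), in 19 and 27 after quantile normalization and in 24 and 22 after median centring.

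Epithelial markers rose in 3 of 19, also over the list alone, with Krt18 and Krt19 (3.52), and passed camera at a median of 0.04 (adjusted p = 0.0191), which did not hold without wild type replicate 3 (0.0894) or with an estimated correlation (adjusted p = 0.613 with an estimated correlation). Skeletal muscle markers rose in 5 and fell in 1 of 18, also over the list alone, with Tnnc1 at 1.69 (camera adjusted p = 0.0644). That list passed without Dicer null replicate 1 (0.0406), wild type replicate 1 (0.0442) or wild type replicate 2 (0.0394). Endothelial markers had 2 of 16 lower, Erg (-2.10) and Eng (-0.34), neural markers 4 higher and 4 lower of 19, with Dcx at 1.22 and Map2 at -2.39, adipocyte, cartilage and bone markers 2 and 2 of 20, with Cd36 at 1.56, and pluripotency genes 1 and 2 of 26, with Sox2 at -1.17, each the same over the list alone.

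In total 6264 rows (26.8%) were called between Dicer null and wild-type cells, 2605 higher and 3659 lower, with 1453 of at least 2-fold, or 866 with an offset of 50. The higher share was 41.6%, and 54.7% after median centring. The groups did not overlap in 42.8% of rows, against 10% by chance. Median, mean and camera direction differed in sign for cell cycle genes and the leukocyte and adipocyte, cartilage and bone markers. Camera called 9 lists and fry 18, and 0 passed camera with an estimated correlation (5 at an unadjusted p under 0.05), where the lowest adjusted p was 0.0731. Where limma called 0 list members in a direction, 0 passed at an unadjusted p under 0.05 as well, except 1 higher interferon-stimulated gene.

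**Figure D2:**
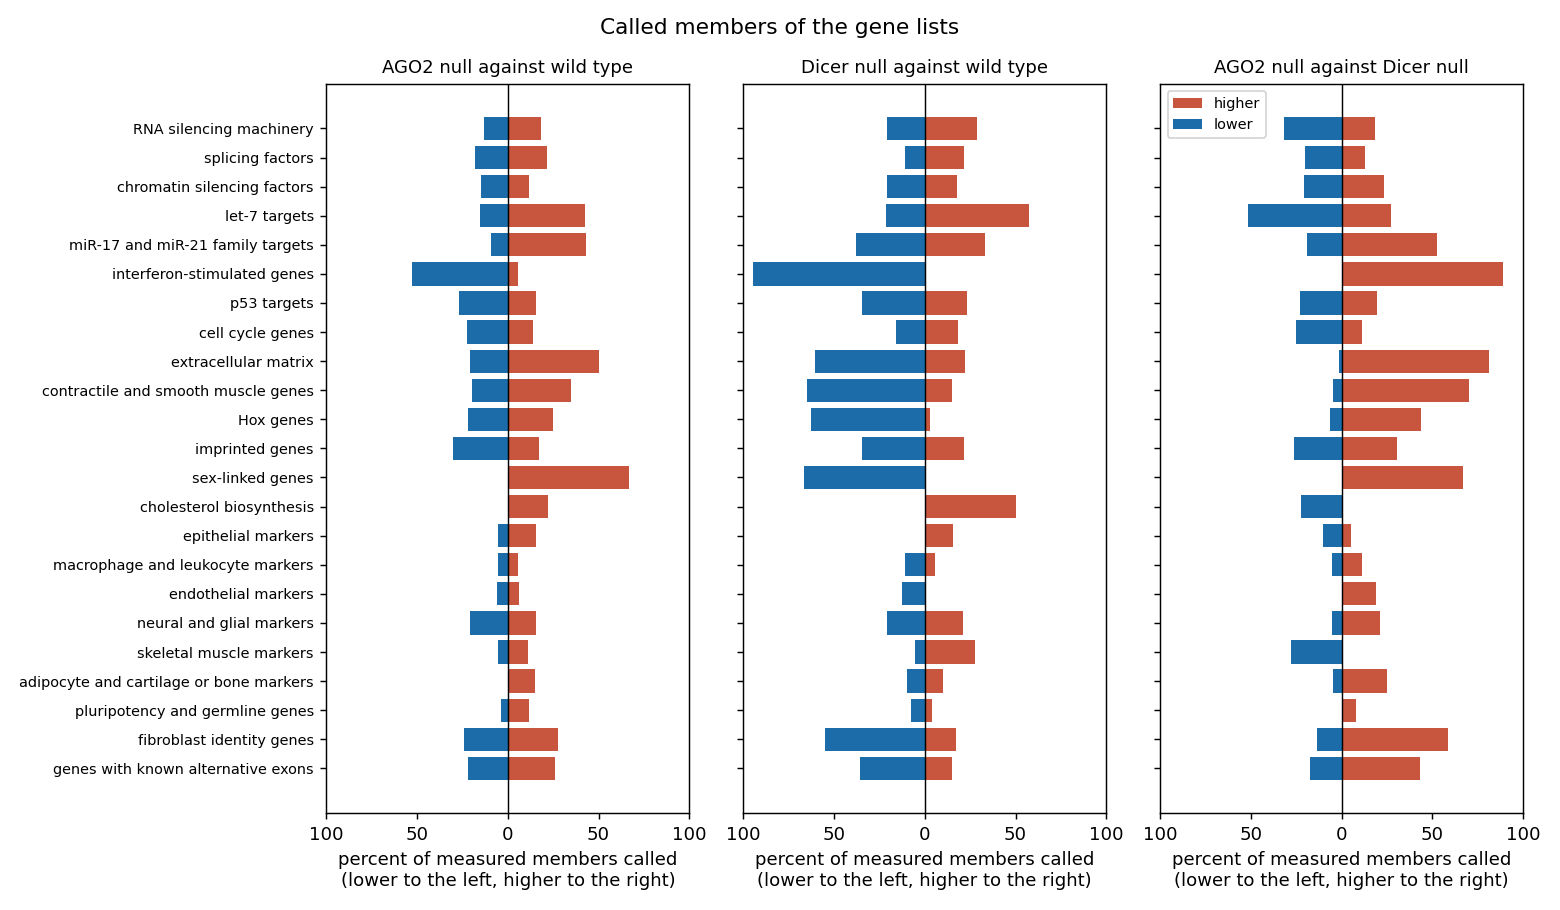
Percent of the measured members of each of the 23 gene lists that were called higher (red, to the right) or lower (blue, to the left) in each of the 3 comparisons. Interferon-stimulated genes are lower in 34 of 36 in Dicer null cells, and extracellular matrix genes are higher in 47 of 58 in AGO2 null against Dicer null cells.

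Compared directly between AGO2 null and Dicer null cells, Ago2 itself differed by -2.37 (adjusted p = 9.02e-07) and Dicer1 by 1.03 (adjusted p = 2.1e-06). Postn was 6.87 higher (SE 0.05, adjusted p = 6.12e-10; 10.79 ± 0.06 against 3.92 ± 0.04, n = 3 each), and Fgf7 5.76, the axon guidance ligand Slit2 5.61, Aspn 5.16, Prrx1 5.14 and the Wnt modulator Sfrp2 4.94 higher. The chemokine Cxcl5 (4.91), Ptn (4.85), Plxdc2 (4.74) and Nrn1 (4.65) followed. Lower in AGO2 null cells were Tmem255a (-5.06), the protease Ctsh (-4.01, SE 0.04, limma adjusted p = 3.51e-09) and Krt18 (-3.71). St8sia1 differed by -3.28, or by -1.78 in its other row. Tnnt2 (-3.10), Eid3 (-2.95) and Bex2 (-2.95) were lower too, as were the epithelial junction or surface genes Perp (-2.93), Dsg2 (-2.89) and Podxl (-2.87). The lines came from different sources, and source and genotype cannot be told apart here.

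Extracellular matrix genes were higher in 47 and lower in 1 of 58 (51 and 1 adjusted over the list alone), with Col12a1 at 4.29 and a median of 0.84 (camera adjusted p = 2.02e-19, adjusted p = 0.0313 with an estimated correlation). Fibroblast identity genes were higher in 17 and lower in 4 of 29 (18 and 4), with Gata4 at -2.61 and a median of 0.90 (camera adjusted p = 4.72e-05, adjusted p = 0.0313 with an estimated correlation). Of the 23 lists, these were the only ones in the 3 comparisons whose camera call held with an estimated correlation. Interferon-stimulated genes were higher in 32 of 36 and lower in none (33 and 0), with Cxcl10 at 3.43 (camera adjusted p = 6.05e-14, adjusted p = 0.191 with an estimated correlation). Contractile genes were higher in 14 and lower in 1 of 20 (15 and 1), with Tagln at 2.68 (camera adjusted p = 4.72e-05, adjusted p = 0.191 with an estimated correlation). Hox genes were higher in 14 and lower in 2 of 32 (15 and 2), with Hoxc8 at 4.06 and Hoxb2 at 3.46. Their camera adjusted p of 0.0308 became 0.0501 without wild type replicate 2 and 0.19 with rows below the median level left out, with adjusted p = 0.191 with an estimated correlation.

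Let-7 targets were lower in 17 and higher in 9 of 33, also over the list alone, with Nr6a1 at -2.49 and Prtg at -2.44 (camera adjusted p = 0.000169, adjusted p = 0.191 with an estimated correlation). RNA silencing genes were lower in 12 and higher in 7 of 38 (13 and 8; camera adjusted p = 0.00368, adjusted p = 0.388 with an estimated correlation), with Lin28a at -2.13. Without Ago2 and Dicer1, a version chosen after seeing the data, 11 of 36 were lower and 6 higher (camera adjusted p = 0.00368). Splicing factors were lower in 11 and higher in 7 of 55 (13 and 8; camera adjusted p = 0.00368, adjusted p = 0.415 with an estimated correlation), with Prpf8 at -0.47. Their split became 4 higher and 23 lower after quantile normalization and 5 and 16 after median centring. Cell cycle genes were lower in 11 and higher in 5 of 44 (12 and 6), with Aurka at -0.52. Their camera adjusted p was 0.0129, 0.0611 without AGO2 null replicate 2, and adjusted p = 0.528 with an estimated correlation, and 3 were higher and 18 lower after quantile normalization. Cholesterol genes were lower in 4 of 18, also over the list alone, and in 7 after quantile normalization (camera adjusted p = 0.000315, adjusted p = 0.568 with an estimated correlation), and skeletal muscle markers in 5 of 18, also over the list alone. The muscle list had a camera adjusted p of 0.00722, adjusted p = 0.262 with an estimated correlation, and 0.0624 with rows below the median level left out.

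Lists that did not pass here were miR-17 and miR-21 family targets (11 higher and 4 lower of 21; 13 and 4 adjusted over the list alone), chromatin silencing factors (8 and 7 of 34; 8 and 8), p53 targets (5 and 6 of 26; 6 and 6), imprinted genes (7 and 6 of 23, also over the list alone) and genes with known alternative exons (35 and 14 of 81; 37 and 16). Chromatin factors turned to 1 higher and 11 lower after quantile normalization and then passed camera (0.00769), and to 4 and 8 after median centring. Imprinted genes turned to 5 and 6 after quantile normalization, and genes with known alternative exons became 30 and 23. The sex-linked genes Kdm5d (1.38) and Eif2s3y (1.19) were higher. Epithelial markers had 1 higher and 2 lower of 19, leukocyte markers 2 and 1 of 18, adipocyte, cartilage and bone markers 5 and 1 of 20, neural markers 4 and 1 of 19 and pluripotency genes 2 and 0 of 26, each the same over the list alone, and endothelial markers 3 and 0 of 16 (2 and 0). Epithelial markers passed camera with rows below the median level left out (0.0292).

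Between the null lines 6140 rows (26.3%) were called, 3935 higher and 2205 lower in AGO2 null cells, with 1273 of at least 2-fold, or 635 with an offset of 50. The higher share of 64.1% became 47.5% after quantile normalization, 54% after median centring and 74.4% with gene levels taken from the exon-level table. The groups did not overlap in 41.2% of rows, against 10% by chance. Camera called 11 lists, 2 of them with an estimated correlation, and fry 17. Median, mean and camera direction differed in sign for chromatin silencing factors, p53 targets, imprinted genes, pluripotency genes and the epithelial, leukocyte and skeletal muscle markers. Where limma called 0 list members in a direction, 0 passed at an unadjusted p under 0.05 as well, except 1 lower pluripotency gene.

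The changes of the 2 null lines against the wild type overlapped. Cadm1, Rtn1 and Lpl rose in both lines (Lpl 4.27 and 3.35), and H19, Crabp1, Mecom and Angpt1 fell in both. Of 3071 rows called in both comparisons, 1274 were higher and 1322 lower in both lines, where independent lists would give 308.6 and 335.4. A further 475 changed in opposite directions, where independent lists would give 672.3, and 360 of these were higher in AGO2 null cells. Examples were Has2 (2.16 in AGO2 null and -1.92 in Dicer null cells), Hoxc8 (1.79 and -2.27), Igf1 (2.10 and -1.55), Sfrp2 (1.58 and -3.36), Thy1 (1.00 and -3.16) and Ctsh (-2.05 and 1.96). These examples, and Thy1 as a gene outside the fixed rule, were chosen after their values were seen. Across rows, which are not independent replicates, the differences correlated at r = 0.509, against 0.497 in 20 simulations of unchanged groups sharing the wild-type samples, in which 0 rows were called in both comparisons by limma. With no changed rows that 0 was all but fixed in advance, so it does not show how many shared calls the common controls add. The covariance was 0.148 against a simulated 0.0171, a difference of 0.131. The 3 wild-type samples cannot be divided into parts of at least 2, so part of the excess overlap may come from the shared controls.

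**Figure D3:**
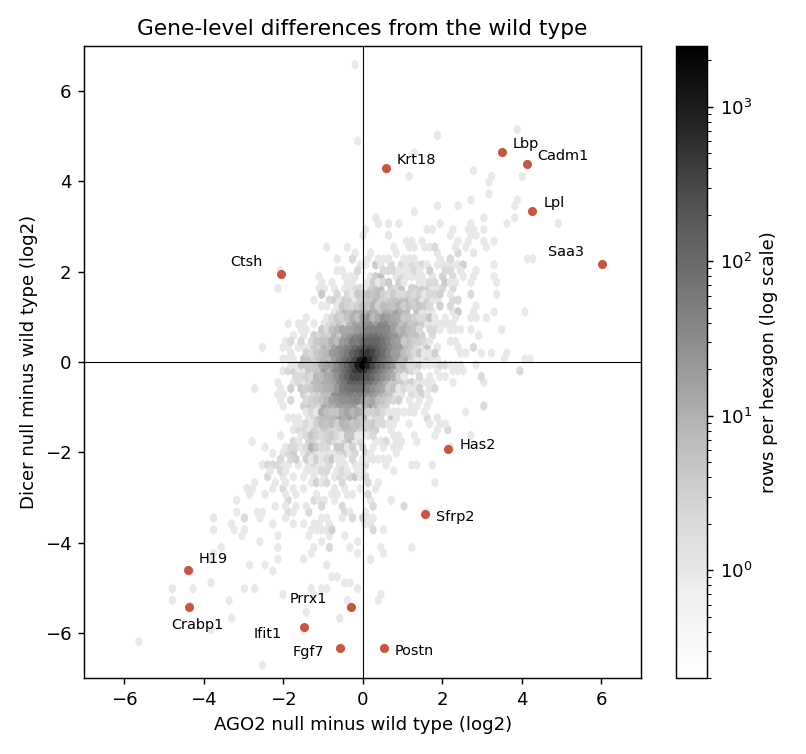
Gene-level log2 differences of AGO2 null (horizontal) and Dicer null cells (vertical) from the wild type over all 23332 rows, shaded by the number of rows per hexagon on a log scale, with named genes as red points. Saa3 is far to the right at 6.02, Postn and Fgf7 lie at the bottom at -6.34, and Has2 and Ctsh lie in opposite quadrants.

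The splicing index differed between AGO2 null and wild-type cells at single probe sets of genes with steady levels. True exon usage and sequence variants under the probes were not told apart for these. Psmb5, a catalytic subunit of the proteasome, had probe set 5037994 at 9.70 ± 0.08 in AGO2 null and 3.97 ± 0.11 in wild-type cells (n = 3), a splicing index difference of 5.56 (SE 0.10, adjusted p = 1.65e-07) while the gene itself differed by 0.18. The ubiquitin ligase subunit Fbxl5 (5.13) and Rint1 (4.54) had a probe set of the same kind, dim in the wild type at 3.48 and 3.01 and bright in both null lines. In Washc5 (-3.86) and Ociad1 (-3.85) the probe set was lower in AGO2 null cells, at 5.53 and 3.53 against 9.19 and 7.22 in the wild type. Large differences also included those of Tnfsf18 (-5.01), Rtn1 (4.78), Mme (4.21), Avpr1a (3.89) and Rbp4 (3.85), whose genes changed themselves. The Mme probe set 4958394 was flat, at 5.75 and 5.45, while its gene fell by 3.91 in the exon-level table.

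Among 83 tested genes with known alternative exons, 158 of 2037 probe sets in 55 genes were called (7.8%, against 5.9% of other probe sets; 210 adjusted over the list alone). Named by the fixed rule were the splicing regulators Mbnl2 (-1.31) and Mbnl1 (-0.83), Arhgap17 (-1.47), Col12a1 (2.11) and the integrin Itga6 (1.16, with a flat probe set and a falling gene). None of the 16 tested probe sets of Cd44, a gene with many variable exons, passed limma's test, 0 at an unadjusted p under 0.05 and 0 with diffSplice, with index differences from -0.60 to 0.15.

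Altogether 6744 of 114158 probe sets (5.9%) in 3030 genes were called, 2860 higher and 3884 lower, 1690 of them at least 2-fold. The higher share was 42.4%, 60.6% with diffSplice and 51.8% with the deposited gene level. Of these calls 3180 lay in genes whose own level differed by less than 0.5, 489 of them at least 2-fold. With p adjusted over the 91454 probe sets of such genes alone, 1348 probe sets of 973 genes were called, 379 at least 2-fold. The count fell to 3355 without AGO2 null replicate 1, 2878 without AGO2 null replicate 3, 3965 without wild type replicate 2 and 2646 in a fit of the 6 samples compared.

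The splicing index also differed between Dicer null and wild-type cells. Zfp503 probe set 5347065 stood at 4.01 against 10.99 in the wild type (index difference -5.92, SE 0.15, limma adjusted p = 1.16e-06). Col11a1 probe set 4428169 stood at 3.21 against 10.53 (-5.73) and Col1a2 probe set 4818225 at 4.13 against 11.91 (-4.84). Each fell further than the median of its gene's probe sets. Exon usage and a median that moved less because of flat probe sets were not told apart here. Psmb5 again had the bright probe set (5.27). In Prrx1 (5.19), Rbp4 (5.04), Colec12 (4.93), Crabp1 (4.90), Gas2 (4.83) and Tnnt2 (-5.04) the probe set moved little while the gene changed strongly, as in Prrx1 with 7.27 and 7.65 against a gene difference of -5.57.

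Of the 2037 probe sets of genes with known alternative exons 212 in 35 genes were called (10.4%, against 6.7% of others; 252 adjusted over the list alone), with Col12a1 (3.97), Vcan (2.73), Postn (2.46) and Tnc (2.09) beside Col11a1. The genes Col12a1 (-3.75) and Postn (-6.34) themselves fell, so their index differences went against the gene. Listed and other probe sets were not matched for the change of the gene in any comparison, although the share of calls rose with it. In Cd44, 9 of 16 probe sets were called, with index differences of all 16 from -2.16 to 0.19. The 9 were the bright ones, at 9.98 to 11.84 in the wild type, and the 7 others were dim, at 5.95 to 7.32. The Cd44 gene fell by 1.20 (adjusted p = 0.000431), and several of its probe sets lost their call with diffSplice or with the deposited gene level.

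In total 7727 probe sets (6.8%) in 2595 genes were called, 3731 higher and 3996 lower, 2844 at least 2-fold. The higher share was 48.3%, and turned to 54.5% with diffSplice, 51.5% with no filter on dim probe sets, 50.7% with the deposited gene level and 50.5% without wild type replicate 1. Of the calls 1962 lay in genes whose own level differed by less than 0.5. With p adjusted over the 80944 probe sets of such genes alone, 602 in 373 genes were called, 40.7% of them higher. The count was 5104, 5120 and 5002 without Dicer null replicate 1, 2 and 3, and 2800 with a stricter filter on dim probe sets.

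Between the null lines, Metap2 probe set 4566345 stood at 10.65 in AGO2 null and 5.71 in Dicer null cells with a gene difference of 0.01 (index difference 4.93), and Ociad1 probe set 5149852 at 3.53 against 8.17 (-4.55). Eln, the elastin gene, had a probe set at 10.18 against 3.61 (4.98). Col11a1 (5.24), Zfp503 (4.92) and Col1a2 (4.61) were higher, and flat probe sets of the strongly changed genes Sfrp2 (-5.05), Prrx1 (-4.84), Colec12 (-4.66) and Apbb1ip (-4.48) received the opposite sign. Of the probe sets of genes with known alternative exons 253 in 54 genes were called (12.4%, against 5.8% of others; 336 adjusted over the list alone), and 8 of 16 in Cd44. Altogether 6807 probe sets (6%) in 2895 genes were called, 3051 higher and 3756 lower, 2221 at least 2-fold. The higher share was 44.8%, and 53.5% with diffSplice. Of the calls 2377 lay in genes whose own level differed by less than 0.5, and with p adjusted over the 84309 probe sets of such genes alone 910 in 694 genes were called. The count was 4153 and 3775 without AGO2 null replicate 1 and 3, 4012, 4166 and 3919 without Dicer null replicate 1, 2 and 3, and 2893 with a stricter filter on dim probe sets. Scaling moved the median of all exon-level differences between the null lines by -0.14 (quantile) and -0.15 (median centring), a shift that the index subtracts within each gene.

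The share of probe sets called rose with the change of the gene. It was 2.96% in AGO2 null, 1.74% in Dicer null and 2.37% in the comparison of the null lines for genes that differed by less than 0.25, and 37.8%, 46.7% and 44.6% for genes that differed by 2 or more. A total of 2664 probe sets were called in both comparisons with the wild type, 1184 higher and 1331 lower in both and 149 in opposite directions, where independent lists would give 93.5, 136 and 227.1. The correlation was 0.519 against 0.501 in 10 simulations, in which 0 were called in both by limma, and the covariance 0.0723 against 0.0161. That 0 too was all but fixed in advance, because the simulations held no changed probe sets. As at the gene level, part of the excess may come from the shared controls. The overlap in the same direction, 2515 probe sets, fell to 1555 and 1472 without AGO2 null replicate 1 and 3, and to 1617, 1598 and 1619 without Dicer null replicate 1, 2 and 3.

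**Figure D4:**
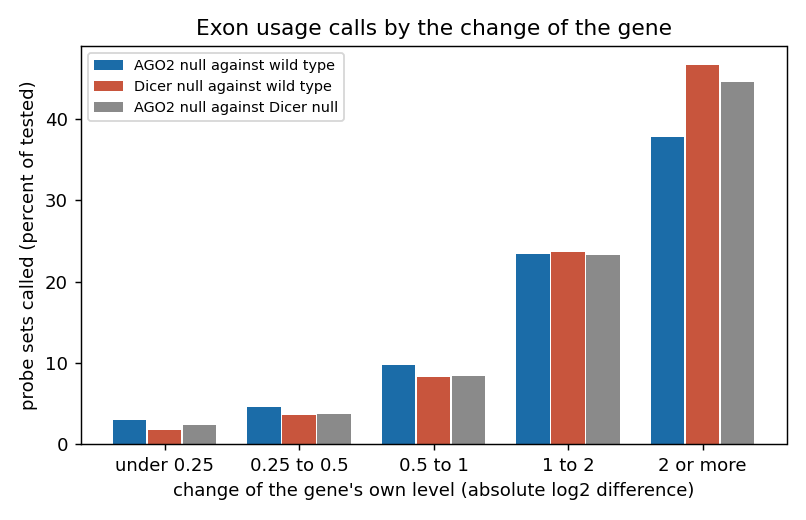
Percent of tested probe sets called for exon usage (vertical) in 5 classes of genes by the absolute log2 difference of the gene (horizontal), with a bar per comparison. The bars stand between 1.74% and 2.96% in the steadiest class and between 37.8% and 46.7% in the class of the largest changes.

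**Figure D5:**
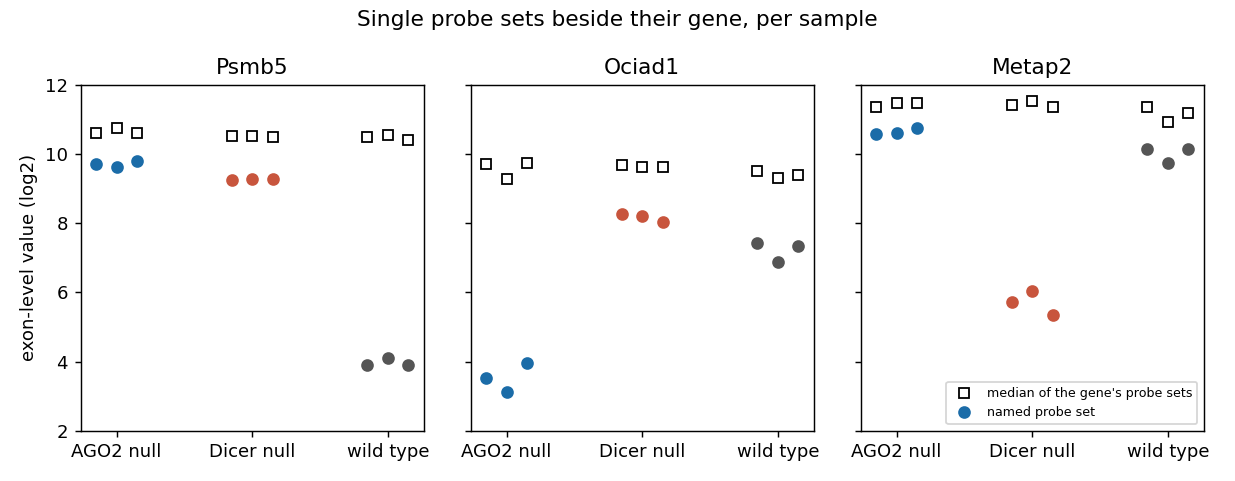
Exon-level log2 values of single probe sets and of the median of their gene, for Psmb5, Ociad1 and Metap2, with a filled point per sample for the probe set and an open square for the gene in the 3 genotypes. The Psmb5 probe set stands at 3.97 in wild-type cells and at 9.70 and 9.27 in AGO2 null and Dicer null cells while the gene differs by 0.18 and 0.03 from the wild type.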

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

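All tests of explanations in this part were chosen after the results they bear on had been seen.

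The extracellular matrix list stood out because camera called it in every comparison, in opposite directions in the 2 null lines against the wild type. Its median was 0.844 in AGO2 null minus Dicer null cells (camera adjusted p = 2.02e-19, adjusted p = 0.0313 with an estimated correlation). Against the wild type the list median was 0.25 in AGO2 null cells and -0.65 in Dicer null cells. Neither of these calls held by camera with an estimated correlation (adjusted p = 0.878 and 0.194). A second result concerned 475 gene-level rows that were called in opposite directions in the 2 null lines against the wild type, 360 of them higher in AGO2 null cells. Independent lists would give 672.3. All 475 were also called between the lines, which follows from their opposite directions and adds no further evidence. The genotypes were 1 line each and the AGO2 null line came from another source, so the lost gene and the origin of the line remain open for both results.

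Changes shared by the null lines were weighed against the noise of the shared wild-type samples. The covariance of the gene-level differences was 8.67 times the simulated covariance of unchanged groups, which argues against that noise as the whole source. A hypothesis is that both null lines may have a more mesothelial-like cell makeup than the wild-type line. Of 13 measured mesothelial genes outside the rule for named genes, 8 were higher in both lines. The list was written after the gene-level values had been seen, so this count gives the hypothesis no independent support. A mesothelial-like makeup, a change of cell state and a different origin of the lines cannot be told apart, because a rise of these genes would look the same under each. Upk1b, Gpm6a and Upk3b, which rose in both, stood at 10.22, 9.85 and 8.97 in the wild type too.

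Lower interferon-stimulated genes in Dicer null cells were weighed against scaling and against leukocytes in the wild-type cultures. After quantile normalization the list median was -1.563, so scaling is not its source. Of 18 leukocyte markers only Cd68 was at or above the median of all rows in the wild type, and it differed by -0.75 in Dicer null cells. Cd14 fell by 0.50, Csf1r rose by 1.11 and the other 15 were not called. The median of the set was 5.23 in wild-type, 5.26 in AGO2 null and 5.27 in Dicer null cells. These values give leukocytes little support, but markers this dim do not exclude them. A different interferon tone of the lines, by loss of Dicer or by their history, was not tested and stays open as well.

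Each comparison of 3 against 3 samples makes 10 splits, so the smallest share is 0.1, too few for a share under 0.05. Every split but the real one also mixes both lines in each group, which moves most of their difference into the spread. Low gene and exon counts there were therefore fixed in advance, and the list counts still carry part of the difference. No conclusion is drawn from these counts. For gene-level calls, 1 split of 10, the real one, gave as many rows in each comparison, with 4903, 6264 and 6140 calls for AGO2 null against wild type, Dicer null against wild type and AGO2 null against Dicer null, and at most 1, 0 and 0 in the others. For exon usage, 1 split of 10 again gave as many, with 6744, 7727 and 6807 calls and at most 0 in the others by limma. For list tests by camera, 5, 2 and 1 of the 10 splits gave as many calls, with real values of 2, 9 and 11 and highest others of 4, 9 and 7.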

How the results depend on the processing

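All alternatives in this part were planned, except the RNA silencing list without Ago2 and Dicer1, chosen after seeing the data, which changed no call. Values were counted as unchanged if they kept their call and its direction, or were called in neither version. The signs of values called in neither were not compared. Of the values of single named genes under the alternatives, 4598 were unchanged, 114 lost the call and 2 turned sign without a call. For named probe sets 4962 were unchanged, 66 gained the call, 168 lost it and 2 turned sign. For list tests 865 were unchanged, 8 gained and 27 lost the call. The cause was not tested where none is given.

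With an offset of 50, which by construction shrinks differences at dim values, rows of at least 2-fold numbered 520, 866 and 635 (AGO2 null against wild type, Dicer null against wild type, AGO2 null against Dicer null). Probe sets of at least 2-fold numbered 992 in the first and 1287 in the third comparison. Requiring 2-fold in both comparisons with the wild type left an overlap in the same direction of 488 rows and 768 probe sets, by construction. List calls numbered 0, 0 and 2 with an estimated correlation, where camera called 2, 9 and 11 and fry 13, 18 and 17, and 1 in the first comparison with rows below the 50th percentile left out. Exon usage calls in genes changed by less than 0.5, which tests fewer genes, numbered 1348, 602 and 910, of which 379, 221 and 294 were at least 2-fold. A stricter filter, which tests fewer probe sets, gave 2800 in the second and 2893 in the third comparison, and 468, 559 and 521 of at least 2-fold, while no filter gave 3246, 5660 and 4351 of at least 2-fold. A fit of the 6 samples compared, with fewer degrees of freedom, gave 2646 in the first. Dicer1 in AGO2 null cells differed by 0.298 as the median of its exon probe sets. That median had no test of its own. It was counted as a lost call because only 6 of the 40 probe sets were called higher.

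Sign reversals of called values were Fdps (-0.084) and Aif1 (-0.035) in AGO2 null cells with gene levels from the exon-level table. At the exon level they were Ago2 probe set 5328180 (0.504, offset of 50) between the null lines and Cd44 probe set 5257188 (0.017, diffSplice) in Dicer null cells. The cause was not tested.

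Leaving out single replicates gave 3886 to 5137, 5037 to 7080 and 4740 to 6325 gene-level calls, and 917 to 1010, 1389 to 1465 and 1150 to 1405 of at least 2-fold. Gene-level overlap in the same direction (2596 with all samples) ranged from 2105 to 2776, list calls from 2 to 3, 9 to 10 and 10 to 11. Exon usage calls ranged from 2878 (without AGO2 null replicate 3) to 6801, 5002 (without Dicer null replicate 3) to 8109, and 3775 (without AGO2 null replicate 3) to 7467. Those of at least 2-fold ranged from 1321 to 1916, 2561 to 2854 and 1885 to 2300, and exon overlap in the same direction (2515 with all samples) from 1472 (without AGO2 null replicate 3) to 2391. Exon counts were also more than 1.5 times lower without AGO2 null replicate 1 (3355 and 4153 in the first and the third comparison, overlap 1555) and wild type replicate 2 (3965 in the first). The same held without Dicer null replicates 1 and 2 (5104 and 5120 in the second, 4012 and 4166 in the third, overlap 1617 and 1598) and, for the third comparison and the overlap, Dicer null replicate 3 (3919 and 1619). Ago2 in AGO2 null cells ranged from -1.53 to -1.40 and Dicer1 in Dicer null cells from -0.83 to -0.79.

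Replicate numbers did not clearly pair the samples. Deviations of samples with the same number correlated from -0.097 to 0.191 at the gene level and -0.087 to 0.176 at the exon level, over 0.1 in 1 of 9 pairs each. With different numbers they ran from -0.18 to 0.139 and from -0.133 to 0.071. Same-number pairs of AGO2 null and wild type were all positive at both levels, and those of the other comparisons mostly negative. A replicate effect shared by AGO2 null and wild type is not excluded. With the replicate block, calls numbered 4223, 5823 and 5553 at the gene level and 4796, 6465 and 5335 for exon usage, overlaps in the same direction 2281 and 1908, and list calls 2, 9 and 11.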

Other observations

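All tests and lists in this part were chosen after the gene-level or exon-level results had been seen.

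Mesothelial genes were higher in both null lines. Of 18 measured, 14 rose and 0 fell by limma in AGO2 null cells, 0 also at an unadjusted p under 0.05 (median 1.88), and 13 rose and 1 fell in Dicer null cells (median 2.02). Lrrn4 (3.06 and 3.01), Bnc1 (2.71 and 2.70), Upk3b (2.39 and 2.71), Gpm6a (2.19 and 2.14) and Upk1b (2.03 and 1.89) rose in both lines by similar amounts, and the mesothelial antigen Msln by 0.57 and 0.87. Between the null lines 6 were higher and 5 lower. Because the rule for named genes had singled out 5 of the 18 before the list was written, it was tested on the other 13. Their values were also known by then, so the p-values describe the list and are no independent evidence. Of these, 9 rose and 0 fell by limma in AGO2 null cells, 0 also at an unadjusted p under 0.05 (camera adjusted p = 5.23e-09, adjusted p = 0.056 with an estimated correlation). In Dicer null cells 8 rose and 1 fell (4.58e-06, adjusted p = 0.0854 with an estimated correlation). The other lists of this part were tested in the same way, with the same limit. Of 17 limb mesenchyme genes, 9 of which are also in lists of the report, 6 were lower and 2 higher in AGO2 null cells (camera adjusted p = 0.0422, adjusted p = 0.126 with an estimated correlation). In Dicer null cells 8 were lower and 3 higher (0.0823). Of 10 retinoic acid pathway genes 5 were lower and 2 higher in AGO2 null cells (0.055), and 5 and 1 in Dicer null cells (0.0823), without passing.

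Of 12 acute phase and innate soluble factors left without Saa3, Lbp and Cxcl5, 8 were higher and 0 lower in AGO2 null cells by limma, 0 also at an unadjusted p under 0.05 (median 0.61, camera adjusted p = 4.52e-05, adjusted p = 0.126 with an estimated correlation), with Hp at 2.08 and Ccl2 at 1.93. In Dicer null cells 3 were higher and 2 lower (camera adjusted p = 0.269). The 3 left out differed by 6.02, 3.51 and -0.34 in AGO2 null and by 2.18, 4.66 and -5.25 in Dicer null cells. Glutathione and Nrf2 target genes were higher in 6 of 12 and lower in 0 by limma in AGO2 null cells, with 2 lower at an unadjusted p under 0.05 (0.0332, adjusted p = 0.189 with an estimated correlation) and in 6, with 1 lower, in Dicer null cells (0.000491, adjusted p = 0.097 with an estimated correlation), with Gsta3 at 3.81 and 3.45 and Mgst1 at 2.05 and 1.76. Genes of type I interferon induction and reception, 6 of which are also in lists of the report, were lower in 12 of 17 and higher in 1 in Dicer null cells (median -0.70, camera adjusted p = 4.58e-06, adjusted p = 0.0854 with an estimated correlation). In AGO2 null cells 6 were lower and 3 higher (0.0422, adjusted p = 0.256 with an estimated correlation).

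Exon usage calls in genes that changed strongly may come from probe sets that do not follow their gene. In genes changed by 1 or more, 63.8%, 59.9% and 62.8% of the calls of the 3 comparisons went against the direction of the gene. The others went with it, a direction that a flat probe set, which does not follow its gene, cannot itself receive. The gene's level is the median of its probe sets, and flat ones can make that median change less. Probe sets that do follow the gene can then be called in its direction. Flat probe sets and true exon usage therefore cannot be told apart in either direction. A share between 50% and 90% decided neither way for the calls as a whole. A flat probe set differs from its gene by no more than the gene's own change. In steady genes, changed by less than 0.25, it therefore cannot itself receive a call of 1 or more. That change was measured on the median of the same probe sets. Many flat ones could thus hide a change of the gene, which was not tested. Smaller calls in steady genes were not tested in this way. Calls of 1 or more made up at least 14.7% of the calls in steady genes. In AGO2 null against wild-type cells these were 287 probe sets, of which 139 had the AGO2 null line apart from both others and 87 the wild type. In Dicer null against wild-type cells they were 129, with the Dicer null line apart in 45 and the wild type in 52, and between the null lines 230, with the AGO2 null line apart in 138 and the Dicer null line in 58. For these, sequence variants between the lines under the probes and true exon usage cannot be told apart, because neither the sequence of the lines nor that of the probes was used here.

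Examples of such probe sets outside the rule for named genes, chosen after their values were seen, were Rif1 probe set 5037048, at 2.67 in AGO2 null cells against 7.69 in Dicer null and 6.32 in wild-type cells, and Pdhb probe set 5510618, at 4.38 in Dicer null cells against 8.52 and 8.19. Psma3 probe set 5370051 stood at 10.94 in AGO2 null cells against 7.68 and 7.30. AGO2 null replicate 2 stood apart from the other samples of its group on the third principal component, at -34.08 against 20.33 and 18.22, a component with 7.8% of the variance. Wild type replicate 2 was also the lowest of its group there, at -12.79 against 0.42 and 11.65.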
